A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

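Total RNA of Saccharomyces cerevisiae was measured on 4 arrays with 2 colours each, 2 arrays for heat shock and 2 for celastrol. Per the labels, the treated sample was in Cy5 and its own control in Cy3 on every array, and the descriptions name treated over control as the direction. No array had the dyes swapped, so a dye effect of a probe adds to both treatments. It cancels only in the difference between them, and only where its size is equal on all arrays. Whether it is equal was not tested. Probes without an annotated gene had medians of −0.63 and −0.10 after heat shock and −0.26 and −0.45 after celastrol. The heat shock arrays set 39 °C against 30 °C, each for 30 min, and the celastrol arrays set 10 µM celastrol against DMSO, each for 1 h. Strain, medium and growth phase are not given in the sources used here.

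The deposited values, 1 per probe and array, were taken as log2 ratios. Per the labels of the series, duplicate values on a chip were averaged and set relative to the median signal of the chip. The array software, background correction, spot filter and array manufacturer are not given in the sources used here. The log base was read from the values: on heat shock replicate 1 many pairs of values differ by exactly the log2 of small whole-number ratios, and hardly any by natural or decimal logs of them. This check could be made on that array alone, and base 2 was assumed for the other 3 arrays, so fold values after celastrol rest on that assumption. The median over all probes was −0.03 and −0.05 on the heat shock arrays and −0.12 and −0.17 on the celastrol arrays, and the SD was 0.94, 0.58, 0.60 and 0.81. The deposited values were used with no further scaling. Exact zeros, of which the arrays held 44, 47, 7 and 4, were taken as not measured, a choice made after the data were seen.

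Of the 6415 probes, 5619 have 1 gene in the platform's annotation, 76 have several and 720 have none there. All 5619 gene identifiers matched the RefSeq gene table of the R64 assembly, and 0 symbols changed. Probes with several genes were left out. The array names no genome build, so no coordinates are given. Values of the 137 genes with more than 1 probe were averaged. Probes of IDH1, which has 6, had an SD of 0.345 around a mean of 1.30 on heat shock replicate 1. The fit took the 5403 genes measured on all 4 arrays and left out 74. Near-identical gene copies, such as pairs of ribosomal protein genes, the SSA1 and SSA2 chaperones, HXT6 and HXT7, or PHO11 and PHO12, can hybridise to each other's probes, and their values are uncertain to that extent.

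Ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 mean per treatment over all 4 arrays. Both treatments thus share 1 estimate of the spread, with 2 residual degrees of freedom, a prior of 3.12 degrees of freedom and a prior SD of 0.268. With an array left out, the residual spread comes from the 2 arrays of the other treatment alone. Each treatment's mean was tested against 0, and celastrol minus heat shock was tested as a contrast in the same fit. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, and a gene was called at an adjusted p under 0.05. All adjusted p-values of genes are limma's. "Rose" and "fell" refer to called genes. Errors are the SD over 2 arrays for a treatment and limma's SE for a difference.

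Gene lists, 22 in number, were written from textbook knowledge and tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 22 lists of a comparison. The lists hold Hsf1 chaperones, Msn2/Msn4 general stress genes, Yap1 oxidative stress genes, the proteasome, the ubiquitin and Cdc48 system, Pdr1/Pdr3 drug resistance genes, sulfur amino acid genes, ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, the unfolded protein response, ergosterol synthesis, the iron regulon, copper and zinc genes, glycolysis, the citric acid cycle and respiration, the cell wall, Gcn4 amino acid genes, histones, G1 genes, mating genes and reference genes. Camera sets a list against all other genes, so its direction can differ from the sign of the list's own median. Beside each list stand the number of called members over all genes and the number when p-values are adjusted over the list alone.

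Named genes were taken by a rule. It took the 10 highest and 10 lowest called genes of each comparison whose arrays all had the same direction, a panel of 20 stress and reference genes, and up to 4 members of each list with the largest change. Which of the list examples are printed was decided after their values were seen, and so was the naming of genes behind counts of 5 or fewer. Treatments were also compared by the correlation of their mean ratios across genes and by Fisher's exact test of the overlap of called genes. Genes are not independent replicates, so the correlation carries no p and the exact test is a description.

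The groups, tests, lists, rule and a first set of other settings were fixed before the data were examined. These settings were median-centred arrays, quantile normalization, equal spread of arrays, genes measured on at least 1 array per treatment, single probes, a robust prior, omission of genes whose replicates differ by more than 1 log2 unit, the replicate number as a block, each array left out in turn, array weights, a test against a 1.5-fold change, and each treatment fitted alone. For gene lists they were an estimated correlation and ranks. With an estimated correlation, camera tests on the 2 residual degrees of freedom, which leaves little power. A call lost there is thus no measure of correlation between the genes of a list. Settings added after seeing the data kept exact zeros, left out faint spots (a recovered control intensity of 200 or less), crossed the replicate numbers, or left out genes below 0 on all arrays with a mean of −1 or less. The recovered intensity is the smallest denominator, up to 1000, that gave a ratio on heat shock replicate 1 as a whole-number fraction. A brighter spot can reduce to a small denominator. Quantile normalization and equal spread for the list tests were also added then. A further 6 lists, on meiosis, Bas1 purine and one-carbon genes, aminoacyl-tRNA synthetases, hexose transporters, Pho4 phosphate genes and fatty acid synthesis, were written after values had been seen and appear only in the closing section, tested on the members not seen before.

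The fit was tested on simulated ratios for 5403 genes, of which 50 were changed at each fold. Noise was independent between genes, with a spread drawn from the fitted prior and equal on all 4 arrays. For heat shock the fit recovered 28% of 2-fold and 80% of 4-fold changes, for celastrol 20% and 94%, and for the difference 0% and 66%. The real arrays differed in spread and real genes are not independent, so these rates need not hold for each treatment. The number of arrays limits the precision. The labels describe the experiments of a treatment as separate, but do not say whether cultures, days or RNA preparations were separate, so p-values measure only the spread between these arrays, which may be partly technical. Numbers were handled with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.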

Results

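Budding yeast cells were exposed to heat or to celastrol, a plant triterpenoid, and their transcripts were measured on arrays with 6415 probes. On 2 heat shock arrays, RNA of cells held at 39 °C for 30 min was compared with RNA of cells held at 30 °C. On 2 celastrol arrays, RNA of cells given 10 µM celastrol for 1 h was compared with RNA of cells given the solvent DMSO. Each value is the log2 ratio of treated over control on 1 array, and each array carried its own control. The log base was settled on heat shock replicate 1 alone and assumed for the other 3 arrays. The comparisons ask which genes each treatment moved and how the drug's response in heat shock and oxidative stress genes stands beside that to heat. The replicate arrays correlated across the 5403 genes tested with r = 0.66 for heat shock and r = 0.85 for celastrol. Centring each array on its median would shift values after celastrol by 0.117 and the difference between treatments by 0.111 log2 units.

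Heat shock raised chaperone genes and genes of the general stress response, and lowered ribosomal protein genes. HSP26 (YBR072W), which encodes a small heat shock protein that binds unfolding proteins, rose 30.9-fold, a log2 ratio of 4.95 ± 0.53 (SD, n = 2 arrays). The Hsp70 chaperone genes SSA3 (YBL075C) and SSA4 (YER103W) rose 24.6-fold (4.62 ± 0.13) and 19.0-fold (4.25 ± 0.73; all SD, n = 2). GND2 (YGR256W), for a 6-phosphogluconate dehydrogenase of the pentose phosphate pathway, rose 16.0-fold (3.997 ± 1.11, SD, n = 2). At the other end RPL9A (YGL147C), for a protein of the large ribosomal subunit, fell to 0.161 of its control level (−2.64 ± 0.46, SD, n = 2).

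Among the 28 Hsf1 chaperone genes tested, 16 rose and 0 fell after heat shock (21 and 3 adjusted over the list alone), with a median log2 ratio of 1.39. For Hsf1 chaperones, the limma camera adjusted p was 5.57e-10 (adjusted p = 0.323 with an estimated correlation). HSP104, the disaggregase that takes protein aggregates apart, rose 9.59-fold (3.26 ± 0.70), and HSP82, for Hsp90, rose 5.61-fold (2.49 ± 0.10; all SD, n = 2). The small heat shock protein gene HSP42 rose 2.64-fold (1.40 ± 0.01, SD, n = 2). HSP30, for a heat shock protein of the plasma membrane that was in none of the lists, rose 8.98-fold (3.17 ± 1.31, SD, n = 2).

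General stress genes under Msn2 and Msn4 included 16 that rose and 0 that fell among 29 (19 and 0 adjusted over the list alone), with a median of 1.40. For general stress genes, the limma camera adjusted p was 1.17e-10 (adjusted p = 0.323 with an estimated correlation). They included ALD3, for an aldehyde dehydrogenase (3.71 ± 0.93), HSP12, for a small membrane-associated protein (3.17 ± 0.48), SIP18 (2.88 ± 0.32) and CTT1, for catalase T (0.98 ± 0.38; all SD, n = 2). Outside the lists, the hexose transporter gene HXT5 (3.27 ± 0.42) and the transaldolase gene NQM1 (3.28 ± 0.56; all SD, n = 2) were among the 10 highest called genes. These 10 had limma adjusted p-values of 0.00794 to 0.0211, and each was higher on 2 of 2 arrays, as the rule of choice required.

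Of the 34 proteasome genes, 7 rose and 0 fell (28 and 0 adjusted over the list alone), and 33 lay above 0, with a median of 0.88. RPN12 (1.75 ± 0.92) and RPN1 (1.34 ± 0.74; all SD, n = 2), for subunits of the regulatory particle, were among them. In the ubiquitin and Cdc48 system 3 of 24 genes rose and 0 fell (8 and 0 adjusted over the list alone), TMC1 by 1.77 ± 0.38 (SD, n = 2), CUZ1 by 1.06 ± 0.31 (SD, n = 2) and DSK2 by 1.01. The limma camera adjusted p was 1.22e-10 for the proteasome and 0.000319 for the ubiquitin list, with adjusted p = 0.323 with an estimated correlation for both. Without heat shock replicate 2 the ubiquitin list lost its call at adjusted p = 0.0649. RPN4, the transcription factor gene for proteasome subunits, was not tested, because heat shock replicate 1 held an exact 0; its other ratios were 0.04 on heat shock replicate 2 and 0.00 and 0.38 on the celastrol arrays.

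Ribosomal protein genes made up most of the lowest called genes. Of 130, 85 fell and 0 rose after heat shock (114 and 0 adjusted over the list alone), with a median of −1.57 (−0.94 without the genes low on all arrays, described below). That filter removes 99 of the 130 for their low values, so the median of −0.94 is nearer 0 by construction. For ribosomal protein genes, the limma camera adjusted p was 4.57e-35 (adjusted p = 0.42 with an estimated correlation). RPS8B, RPS22A, RPP2B, RPS4A, RPP1A and RPS14A stood beside RPL9A among the 10 lowest called genes, at log2 ratios of −2.36 to −2.15, as did SSB2, for a ribosome-bound Hsp70 (−2.26 ± 0.60, SD, n = 2). The 10 lowest had limma adjusted p-values of 0.0133 to 0.0415, and each was lower on 2 of 2 arrays, as the rule of choice required. A set of 357 genes, 99 of them ribosomal protein genes, lay below 0 on all 4 arrays with a mean of −1 or less, and 143 of the 259 genes that fell after heat shock belong to it, including 9 of the 10 lowest.

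Histone genes fell in 6 of 9 cases and rose in 0 (9 and 0 adjusted over the list alone), with a median of −1.21. For histone genes, the limma camera adjusted p was 2.49e-06 (adjusted p = 0.416 with an estimated correlation). HTA2, for histone H2A, had a ratio of −1.45 ± 0.08 (SD, n = 2), HTB2, for H2B, −1.42 ± 0.46 (SD, n = 2) and HHF1, for H4, −1.32 ± 0.20 (SD, n = 2). Of 22 G1 cell cycle genes 6 fell and 0 rose (10 and 0 adjusted over the list alone), among them the cyclin gene CLB6 (−1.69 ± 0.28) and POL30, for the replication clamp (−1.46 ± 0.02; all SD, n = 2). The G1 list had a limma camera adjusted p of 0.000171 and an adjusted p = 0.323 with an estimated correlation. Of 26 sulfur amino acid genes 5 fell and 0 rose (6 and 0 adjusted over the list alone). For sulfur genes, the limma camera adjusted p was 0.0153 (adjusted p = 0.331 with an estimated correlation). The members that fell most were SAM1 (−2.22 ± 0.27) and SAM2 (−2.02 ± 0.38), for the enzymes that make S-adenosylmethionine, ahead of MET17, for the enzyme that takes up sulfide (−1.14 ± 0.54), and the S-adenosylmethionine permease gene SAM3 (−1.06 ± 0.05; all SD, n = 2). Without heat shock replicate 2 the sulfur list lost its call at adjusted p = 0.125.

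The other 14 lists were not called after heat shock, although single members changed. Without heat shock replicate 1 the Yap1, ribosome biogenesis, ergosterol, cell wall and mating lists passed, and ribosome biogenesis also did by ranks, with quantile normalization, with equal spread and without the genes low on all arrays. Of 29 cell wall genes 6 rose and 1 fell (10 and 7 adjusted over the list alone; limma camera adjusted p = 0.125), with PST1 (2.54 ± 0.03), HSP150 (2.32 ± 0.20), SED1 (1.99 ± 0.43) and PIR3 (1.96 ± 0.07; all SD, n = 2) the highest. Gcn4 amino acid genes moved both ways, with 4 of 41 higher and 9 lower (8 and 15 adjusted over the list alone; limma camera adjusted p = 0.191). The arginine pathway genes CPA1 (2.65 ± 0.37) and ARG3 (2.55 ± 0.01) rose, while ILV3, for branched-chain amino acid synthesis (−2.14 ± 0.71), and ARO4, for aromatic amino acid synthesis (−1.70 ± 0.11; all SD, n = 2), fell. Of 48 citric acid cycle and respiration genes 6 rose and 2 fell (8 and 4 adjusted over the list alone; limma camera adjusted p = 0.768), with IDH2, for isocitrate dehydrogenase, at 2.12 ± 0.44 (SD, n = 2) and the aconitase gene ACO1 at 1.70 ± 0.01 (SD, n = 2). The list's median was −0.02 and its mean 0.12. Of 24 mating genes 4 fell and 0 rose (7 and 2 adjusted over the list alone; limma camera adjusted p = 0.11), namely PRM6 (−2.28 ± 0.32), FIG1 (−1.57 ± 0.64), AGA2 (−1.54 ± 0.14; all SD, n = 2) and AGA1 (−1.33).

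Yap1 oxidative stress genes were mostly not called after heat shock, with 2 of 30 higher and 1 lower (5 and 2 adjusted over the list alone; limma camera adjusted p = 0.122). Their median was 0.23, and 0.0517 without heat shock replicate 2. The peroxiredoxin gene TSA2 (2.41 ± 0.35) and ECM4, for a glutathione transferase (1.41 ± 0.25), rose, and the thioredoxin gene TRX1 (−1.29 ± 0.24; all SD, n = 2) fell. In the Pdr1/Pdr3 list 1 of 20 rose, the drug pump gene PDR5 (1.11 ± 0.44), and 1 fell, the transporter gene QDR2 (−2.01 ± 0.04; all SD, n = 2), with 1 and 1 adjusted over the list alone (limma camera adjusted p = 0.538). Of 25 genes of the unfolded protein response the oxidoreductase gene ERO1 rose (1.85 ± 0.31), and the phospholipid synthesis genes INO1 (−1.83 ± 0.24) and OPI3 (−1.60 ± 0.46; all SD, n = 2) fell, which makes 1 and 2 (2 and 2 adjusted over the list alone; limma camera adjusted p = 0.866). Ribosome biogenesis had 2 of 70 lower, NOP56 (−1.13 ± 0.15) and DBP2 (−1.004 ± 0.01; all SD, n = 2), and 0 higher (2 and 0 adjusted over the list alone; limma camera adjusted p = 0.0632). Iron regulon genes rose in 3 of 25 cases (ENB1, ISU1 and SMF3, by 1.004, 0.87 and 1.10; 5 adjusted over the list alone; limma camera adjusted p = 0.158). Likewise 1 of 14 copper and zinc genes rose (CRS5, by 0.99; 1 adjusted over the list alone; limma camera adjusted p = 0.0966). Ergosterol synthesis had 1 of 25 lower (ERG20, −1.03; 3 adjusted over the list alone; limma camera adjusted p = 0.519). No member was called among 25 RNA polymerase I and III genes, 18 glycolysis genes and 12 reference genes, 0 also adjusted over the list alone (limma camera adjusted p = 0.323, 0.866 and 0.859). Of the panel's genes, TRX2 (0.32 ± 0.78), TRR1 (−0.05 ± 0.19), GSH1 (−0.20 ± 0.36), OYE3 (−0.15 ± 0.45), GTT2 (0.32 ± 0.14), FLR1 (−0.06 ± 0.08), CUP1-1 (0.43 ± 0.18), FIT2 (0.49 ± 0.09), KAR2 (0.44 ± 0.61) and ACT1 (−0.26 ± 0.10; all SD, n = 2) were not called after heat shock.

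In all, limma called 490 of 5403 genes after heat shock, 231 higher and 259 lower, and with quantile normalization 360 higher and 629 lower. Without the 357 genes low on all arrays, which by construction removes lower calls, it called 277 higher and 155 lower. An unadjusted p under 0.05 was reached by 1645 genes, and the smallest change that was called was 0.75 log2 units. The count was 0 by limma, with 1154 genes at an unadjusted p under 0.05, when either celastrol array was left out or the heat shock arrays were fitted alone, and 1582 without heat shock replicate 2. Of the 58 calls of named genes, all were lost without either celastrol array, 33 in a test against a 1.5-fold change, 14 with array weights and 3 with exact zeros kept as values. CTT1 and MET17 lost theirs with median-centred arrays and PDR5 with equal spread, and without heat shock replicate 1 RPS4A, PDR5, MET17 and RPN1 lost theirs (−1.67, 0.80, −0.76 and 0.81), as CTT1 did without heat shock replicate 2 (0.71).

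Celastrol raised Yap1 oxidative stress genes and Pdr1/Pdr3 drug resistance genes along with chaperone and proteasome genes, and lowered ZRT1. FRM2 (YCL026C-A), for a protein related to nitroreductases, rose 38.0-fold, a log2 ratio of 5.25 ± 0.10 (SD, n = 2 arrays). GRE2 (YOL151W), for a methylglyoxal reductase, rose 32.2-fold (5.01 ± 0.95), and OYE3 (YPL171C), for an NADPH dehydrogenase of the old yellow enzyme family, rose 16.7-fold (4.06 ± 0.73; all SD, n = 2). SSA4 (YER103W), for an Hsp70 chaperone, rose 17.6-fold (4.14 ± 0.63, SD, n = 2). ZRT1 (YGL255W), for the high-affinity zinc transporter, fell to 0.0769 of its control level (−3.70 ± 0.78, SD, n = 2).

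Of the 30 Yap1 oxidative stress genes, 15 rose and 0 fell after celastrol (21 and 0 adjusted over the list alone), with a median of 1.32. For Yap1 genes, the limma camera adjusted p was 4.99e-17 (adjusted p = 0.209 with an estimated correlation). Besides FRM2, GRE2 and OYE3 these included the glutathione transferase genes ECM4 (4.04 ± 0.21) and GTT2 (3.31 ± 0.20), the transporter gene FLR1 (2.72 ± 0.74), the thioredoxin gene TRX2 (2.68 ± 0.16) and GSH1, for the first enzyme of glutathione synthesis (1.46 ± 0.03; all SD, n = 2). The thioredoxin reductase gene TRR1 was at 0.73 ± 0.37 (SD, n = 2) and was not called. Outside this list, the 10 highest called genes also included OSI1 (4.94 ± 0.44), YNL134C (5.06 ± 0.07), YML131W (4.44 ± 0.03), CIS1 (4.23 ± 0.57) and, from the general stress list, YGP1, for a secreted glycoprotein (4.38 ± 0.25; all SD, n = 2). These 10 had limma adjusted p-values of 0.00161 to 0.0242, and each was higher on 2 of 2 arrays, as the rule of choice required.

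Pdr1/Pdr3 drug resistance genes rose in 12 of 20 cases and fell in 0 (16 and 1 adjusted over the list alone), with a median of 0.95. For Pdr1/Pdr3 genes, the limma camera adjusted p was 2.82e-11 (adjusted p = 0.209 with an estimated correlation). The drug pump genes PDR5 (3.31 ± 0.10), YOR1 (2.83 ± 0.02) and SNQ2 (2.77 ± 0.03) were among them, as was the lipid transporter gene RSB1 (2.58 ± 1.13; all SD, n = 2).

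Proteasome genes rose in 27 of 34 cases and fell in 0 (33 and 1 adjusted over the list alone), and 33 lay above 0, with a median of 1.38. For proteasome genes, the limma camera adjusted p was 9.16e-24 (adjusted p = 0.209 with an estimated correlation). ECM29, for a proteasome-associated protein (2.52 ± 0.36), PRE6 (2.02 ± 0.55) and PRE3 (1.90 ± 0.28; all SD, n = 2), for core particle subunits, rose 5.75-, 4.06- and 3.73-fold. In the ubiquitin and Cdc48 system 9 of 24 genes rose and 0 fell (13 and 0 adjusted over the list alone). For the ubiquitin list, the limma camera adjusted p was 2.2e-09 (adjusted p = 0.209 with an estimated correlation). TMC1 (2.08 ± 0.14), the ubiquitin-activating enzyme gene UBA1 (1.91 ± 0.12), CUZ1 (1.90 ± 0.04) and UFD1, for a Cdc48 cofactor (1.80 ± 0.34; all SD, n = 2), were the highest.

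Hsf1 chaperone genes rose in 14 of 28 cases and fell in 1, CUR1 at −1.13 (18 and 2 adjusted over the list alone), with a median of 0.96. For Hsf1 chaperones, the limma camera adjusted p was 5.7e-11 (adjusted p = 0.299 with an estimated correlation). Beside SSA4 they included the polyubiquitin gene UBI4 (2.94 ± 0.53), SSA2 (2.88 ± 0.60), HSP26 (2.71 ± 0.34), HSP104 (2.01 ± 0.68), HSP82 (1.80 ± 0.15) and HSP42 (1.20 ± 0.54; all SD, n = 2). Of the 29 general stress genes 3 rose, YGP1, the hexokinase gene HXK1 (1.48 ± 0.22) and the repressor gene XBP1 (1.34 ± 0.37; all SD, n = 2), and 0 fell (8 and 1 adjusted over the list alone), with a median of 0.25. For general stress genes, the limma camera adjusted p was 0.00279 (adjusted p = 0.4 with an estimated correlation). HSP12 (−0.67 ± 0.79) and CTT1 (−0.00 ± 0.19; all SD, n = 2) were not called.

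Ribosomal protein genes fell after celastrol in 18 of 130 cases and rose in 0 (98 and 0 adjusted over the list alone), with a median of −1.06. The celastrol arrays stood apart, with list medians of −0.65 on replicate 1, the value left without replicate 2, and −1.50 on replicate 2. For ribosomal protein genes, the limma camera adjusted p was 1.28e-18 (adjusted p = 0.436 with an estimated correlation). Of 70 ribosome biogenesis genes 5 fell and 0 rose (27 and 0 adjusted over the list alone) and 0 lay above 0, with the helicase gene DBP2 (−1.62 ± 0.11), KRR1 (−1.15 ± 0.29) and NOP13 (−1.08 ± 0.32; all SD, n = 2) among them. For ribosome biogenesis genes, the limma camera adjusted p was 2.82e-11 (adjusted p = 0.352 with an estimated correlation). No single member of 25 RNA polymerase I and III genes was called, 0 also adjusted over the list alone, and the list's median was −0.43. For polymerase I and III genes, the limma camera adjusted p was 0.00198 (adjusted p = 0.386 with an estimated correlation).

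Histone genes fell in 6 of 9 cases and rose in 0 (9 and 0 adjusted over the list alone), with HTA2 (−2.40 ± 0.32), HTA1 (−2.15 ± 0.44), HTB2 (−1.93 ± 0.28) and HHF1 (−1.83 ± 0.25; all SD, n = 2) the lowest. For histone genes, the limma camera adjusted p was 2.37e-06 (adjusted p = 0.352 with an estimated correlation). No G1 gene among 22 was called over all genes, 1 was higher and 8 lower adjusted over the list alone, and the median was −0.54. For G1 genes, the limma camera adjusted p was 0.0141 (adjusted p = 0.352 with an estimated correlation). The 48 citric acid cycle and respiration genes had 1 higher, the lipoamide dehydrogenase gene LPD1 (1.15 ± 0.03), and 1 lower, the ATP synthase gene ATP20 (−1.34 ± 0.23; all SD, n = 2), also 1 and 1 adjusted over the list alone. Their median was 0.06, above that of all genes at −0.11. For citric acid cycle genes, the limma camera adjusted p was 0.0141 (adjusted p = 0.436 with an estimated correlation).

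After ZRT1, the lowest called genes were SNU13, for a protein of small nucleolar and spliceosomal RNA particles (−2.81 ± 0.33), CHA1, for the serine and threonine deaminase (−2.54 ± 0.02), RPL43A (−2.41 ± 0.77; all SD, n = 2) and HTA2. They were followed by the acid phosphatase genes PHO3 (−2.40 ± 0.28) and PHO11 (−2.24 ± 0.16), the mitochondrial reductase gene ETR1 (−2.35 ± 1.18), the carnitine acetyltransferase gene YAT1 (−2.32 ± 0.94) and the repressor gene TOD6 (−2.22 ± 0.57; all SD, n = 2). The 10 lowest had limma adjusted p-values of 0.00773 to 0.0445, and each was lower on 2 of 2 arrays, as the rule of choice required. Apart from ZRT1 and CHA1 they belong to the set of 357 genes below 0 on all 4 arrays, which holds 74 of the 145 genes that fell after celastrol. The low-affinity zinc transporter gene ZRT2 also fell (−1.59 ± 0.80), while the reductase gene FRE7 rose (1.73 ± 0.23; all SD, n = 2). This makes 1 higher and 2 lower among 14 copper and zinc genes (1 and 2 adjusted over the list alone; limma camera adjusted p = 0.858).

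The other lists not called after celastrol had few called members. Of these the glycolysis list passed without celastrol replicate 1, and the sulfur list with equal spread and without the genes low on all arrays. Sulfur amino acid genes had 4 of 26 higher, including the sulfate assimilation genes MET14 (1.502 ± 0.17) and MET3 (1.26 ± 0.14) and the regulator gene MET28 (1.40 ± 0.16), and 2 lower. The latter were MET17 (−1.36 ± 0.09; all SD, n = 2) and SAM3 (−0.78), with 4 and 2 adjusted over the list alone (limma camera adjusted p = 0.0614). Cell wall genes had 3 of 29 lower and 0 higher (6 and 2 adjusted over the list alone; limma camera adjusted p = 0.279), namely the mannoprotein gene CWP1 (−1.46 ± 0.15), the glucanase gene EXG1 (−1.12 ± 0.12) and FKS1, for glucan synthase (−1.09 ± 0.21; all SD, n = 2). Of 18 glycolysis genes the pyruvate decarboxylase gene PDC1 fell (−1.44 ± 0.09, SD, n = 2), with 0 higher (3 and 0 adjusted over the list alone; limma camera adjusted p = 0.122). Iron regulon genes had 1 of 25 higher, the heme oxygenase gene HMX1 (1.15 ± 0.51), and 1 lower, the copper chaperone gene ATX1 (−1.01 ± 0.03; all SD, n = 2), with 2 and 4 adjusted over the list alone (limma camera adjusted p = 0.657). Ergosterol synthesis had 1 of 25 higher, the squalene synthase gene ERG9 (1.10 ± 0.12, SD, n = 2), and 1 lower, ERG6 (−0.82), also 1 and 1 adjusted over the list alone (limma camera adjusted p = 0.189). In the unfolded protein response 1 of 25 rose, PDI1, for protein disulfide isomerase (1.48 ± 0.34, SD, n = 2), and 0 fell (2 and 0 adjusted over the list alone; limma camera adjusted p = 0.689). Of 41 Gcn4 genes 1 rose, SER3 (0.94), and 1 fell, LEU9 (−0.88), also 1 and 1 adjusted over the list alone (limma camera adjusted p = 0.42). No member was called among 24 mating genes and 12 reference genes, 0 also adjusted over the list alone (limma camera adjusted p = 0.657 and 0.858). Against their own medians of −0.05, −0.10 and −0.01, the camera direction was up for the unfolded protein response, iron and Gcn4 lists, which it sets against all other genes. On median-centred arrays these 3 medians were 0.0626, 0.0124 and 0.104. The mating list had a median of 0.04 and a mean of −0.04. CUP1-1 (−0.08 ± 0.09), FIT2 (0.25 ± 0.26), KAR2 (−0.45 ± 0.39) and ACT1 (0.31 ± 0.13; all SD, n = 2) were not called after celastrol.

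In all, limma called 353 of 5403 genes after celastrol, 208 higher and 145 lower. The split was 249 and 92 with median-centred arrays, 468 and 667 with quantile normalization and 393 and 700 with equal spread. An unadjusted p under 0.05 was reached by 1663 genes, and the smallest change that was called was 0.78 log2 units. Without celastrol replicate 1 or 2 the count was 0 by limma, with 926 and 411 genes at an unadjusted p under 0.05, and without either heat shock array, or with celastrol fitted alone, it was 1522. Of the 65 calls of named genes, all were lost without either celastrol array, 36 in a test against a 1.5-fold change and 6 with exact zeros kept as values. YAT1, MET17, ZRT2 and ATX1 lost theirs with median-centred arrays, and the histone list lost its call when the 357 genes low on all arrays were left out. That filter removes HTA1, HTA2, HTB1, HTB2, HHF1, HHF2 and HHT1 for their low values, so the lost call follows by construction.

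**Figure D1:**
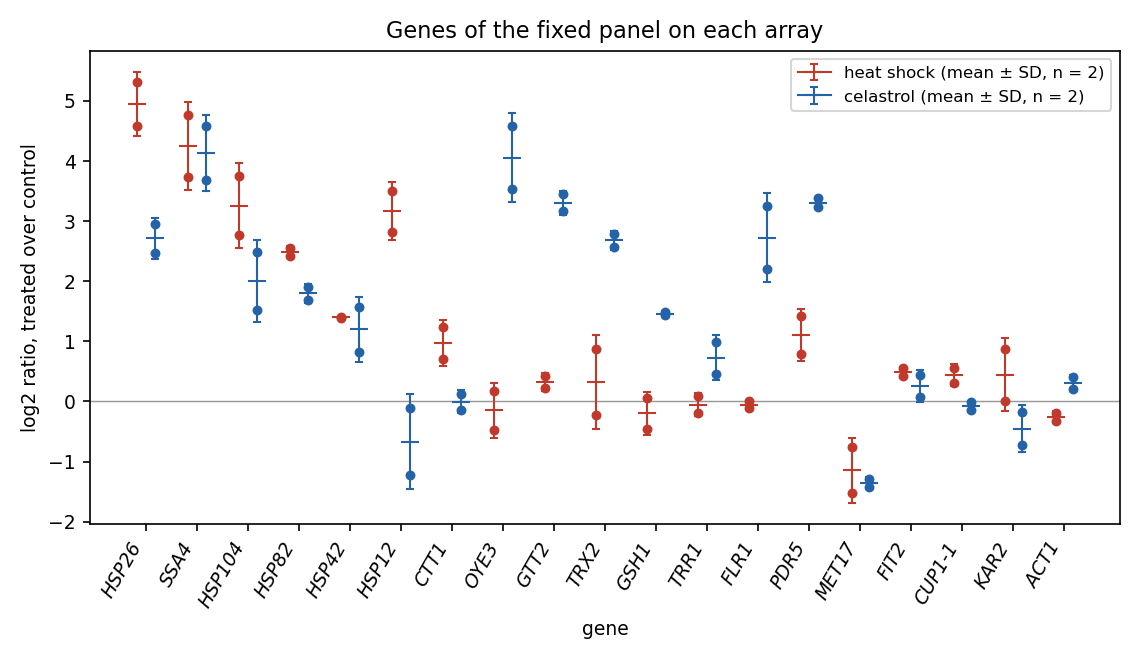
Log2 ratio of treated over control (y axis) for 19 genes of the fixed panel (x axis), with a point for each array and the mean ± SD of 2 arrays, heat shock in red and celastrol in blue. HSP26 and HSP12 stand at 4.95 and 3.17 after heat shock against 2.71 and −0.67 after celastrol, and OYE3 and GTT2 stand at 4.06 and 3.31 after celastrol against −0.15 and 0.32 after heat shock.

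Celastrol and heat shock differed most in FRM2 and OSI1, which were higher after celastrol, and in CHA1 and ZRT1, which were lower. FRM2 was 54.0-fold higher relative to control after celastrol than after heat shock, a difference of 5.76 ± 0.32 log2 units (SE, n = 2 arrays per treatment), with a mean of 5.25 after celastrol and −0.51 after heat shock. OSI1 (YKL071W), known as an oxidative stress-induced gene, differed by 5.62 ± 0.31 (SE, n = 2 per treatment). CHA1 (YCL064C) differed by −4.68 ± 0.44 (SE, n = 2 per treatment), at 2.15 after heat shock and −2.54 after celastrol, and ZRT1 by −4.35 ± 0.41 (SE, n = 2 per treatment). HSP12 and SSA3, stress genes that heat raised, differed by −3.84 ± 0.46 and −3.58 ± 0.26 (SE, n = 2 per treatment).

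The remaining genes among the 10 called with the largest positive difference were YML131W (4.48), YGR035C (4.31), OYE3 (4.21), CIS1 (4.18), YNL134C (4.15), GRE2 (3.94) and the aryl-alcohol dehydrogenase-like genes AAD6 (3.75) and AAD15 (3.50), with SEs of 0.21 to 0.47. Those called with the largest negative difference further included the purine synthesis gene ADE17 (−3.57), YRO2 (−3.45), SIP18 (−3.31), HXT5 (−3.24), ECM13 (−3.23) and NQM1 (−3.13), with SEs of 0.26 to 0.39. These 20 genes had limma adjusted p-values of 0.0107 to 0.0391. In each, both celastrol arrays lay on the same side of both heat shock arrays, as the rule of choice required.

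Yap1 oxidative stress genes were higher after celastrol than after heat shock in 6 of 30 cases and lower in 1, TSA2 at −2.23 (16 and 2 adjusted over the list alone), with a median difference of 1.37. For Yap1 genes, the limma camera adjusted p was 1.32e-14 (adjusted p = 0.233 with an estimated correlation). GTT2 differed by 2.98 ± 0.24 (SE, n = 2 per treatment). TRX2 (2.36 ± 0.41, limma adjusted p = 0.0842), GSH1 (1.66 ± 0.26, adjusted p = 0.0679), FLR1 (2.78 ± 0.39, adjusted p = 0.0536) and TRR1 (0.78 ± 0.28, adjusted p = 0.331) were not called for the difference. Pdr1/Pdr3 genes were higher in 6 of 20 cases and lower in 0 (12 and 0 adjusted over the list alone), with a median difference of 1.09, among them SNQ2 (2.73 ± 0.21), PDR5 (2.20 ± 0.29) and YOR1 (2.19 ± 0.22; all SE, n = 2 per treatment). For Pdr1/Pdr3 genes, the limma camera adjusted p was 3.3e-14 (adjusted p = 0.233 with an estimated correlation). Proteasome genes were called in 0 of 34 cases, 0 also adjusted over the list alone, with 29 above 0 and a median difference of 0.59, and ECM29 stood at 1.26 ± 0.26 (SE, n = 2 per treatment). For proteasome genes, the limma camera adjusted p was 8.17e-10 (adjusted p = 0.324 with an estimated correlation). The ubiquitin and Cdc48 list also had 0 of 24 called, 0 adjusted over the list alone, and a median difference of 0.40 (0.21 without heat shock replicate 1). For the ubiquitin list, the limma camera adjusted p was 0.0011 (adjusted p = 0.324 with an estimated correlation).

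General stress genes were lower after celastrol than after heat shock in 4 of 29 cases and higher in 0 (13 and 3 adjusted over the list alone), with a median difference of −0.93. For general stress genes, the limma camera adjusted p was 9.98e-06 (adjusted p = 0.412 with an estimated correlation). HSP12, SIP18, RTN2 (−1.80) and TKL2 (−2.98) were the 4. The Hsf1 chaperone list was not called as different, with SSA3 lower, 0 higher and a median difference of −0.25, or −0.59 to −0.0834 with an array left out (5 lower and 1 higher adjusted over the list alone; limma camera adjusted p = 0.123). It passed with quantile normalization and without celastrol replicate 2, with adjusted p-values of 0.00166 to 0.781 over all settings tried. SSA4 (−0.11 ± 0.48, which turned to 0.03 with equal spread), HSP82 (−0.69 ± 0.22), HSP42 (−0.20 ± 0.32), HSP104 (−1.25 ± 0.48), HSP26 (−2.24 ± 0.35) and SSA2 (2.05 ± 0.34; all SE, n = 2 per treatment) were not called for the difference. CTT1 (−0.98), CUP1-1 (−0.52), MET17 (−0.21), FIT2 (−0.24), KAR2 (−0.90) and ACT1 (0.57) were not called either.

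Ribosomal protein genes were called in 0 of 130 cases, 0 also adjusted over the list alone, and 113 lay above 0 in the difference, with a median of 0.53. This rests largely on celastrol replicate 1, at a list median of −0.65, since replicate 2 at −1.50 lay between the heat shock arrays at −1.76 and −1.43. The median difference was 0.13 without celastrol replicate 1, 0.90 without celastrol replicate 2 and 0.23 without the genes low on all arrays. For ribosomal protein genes, the limma camera adjusted p was 6.02e-13 (adjusted p = 0.533 with an estimated correlation). Ribosome biogenesis genes had 0 of 70 called, 0 adjusted over the list alone, 5 above 0 and a median of −0.46. For ribosome biogenesis genes, the limma camera adjusted p was 1.22e-06 (adjusted p = 0.416 with an estimated correlation). Sulfur amino acid genes had 1 of 26 called, MET28, which was higher by 2.28 ± 0.23 (SE, n = 2 per treatment), with 6 higher and 0 lower adjusted over the list alone. For sulfur genes, the limma camera adjusted p was 3.63e-06 (adjusted p = 0.233 with an estimated correlation). Cell wall genes had 2 of 29 lower, CWP1 (−2.31 ± 0.29) and PST1 (−2.15 ± 0.22; both SE, n = 2 per treatment), and 0 higher (9 and 0 adjusted over the list alone). For cell wall genes, the limma camera adjusted p was 0.000785 (adjusted p = 0.416 with an estimated correlation).

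A further 5 lists passed for the difference with adjusted p-values near the threshold. Mating genes had 0 of 24 called, 1 higher adjusted over the list alone. For mating genes, the limma camera adjusted p was 0.0144 (adjusted p = 0.533 with an estimated correlation). Gcn4 genes had 2 of 41 lower, ARG3 (−2.50 ± 0.21) and CPA1 (−2.21 ± 0.27; both SE, n = 2 per treatment), although the list's median was 0.18 (0.0215 to 0.42 with a heat shock array left out) and its camera direction was up, with 6 higher and 4 lower adjusted over the list alone. For Gcn4 genes, the limma camera adjusted p was 0.0382 (adjusted p = 0.533 with an estimated correlation). G1 genes had 0 of 22 called, 0 adjusted over the list alone, and RNA polymerase I and III genes 0 of 25, 0 adjusted over the list alone. For G1 genes, the limma camera adjusted p was 0.0382 (adjusted p = 0.416 with an estimated correlation). For polymerase I and III genes, the limma camera adjusted p was 0.0384 (adjusted p = 0.533 with an estimated correlation). Copper and zinc genes had 1 of 14 lower, ZRT1 (2 lower and 1 higher adjusted over the list alone), and ZRT2 stood at −2.27 ± 0.41 (SE, n = 2 per treatment, limma adjusted p = 0.0953). For copper and zinc genes, the limma camera adjusted p was 0.0399 (adjusted p = 0.615 with an estimated correlation). Each of these 5 lost its call when at least 1 of the arrays was left out, all but the mating list without the genes low on all arrays, and the polymerase, Gcn4 and G1 lists with at least 1 of the 3 scalings.

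The remaining lists did not pass for the difference. Without celastrol replicate 1 the glycolysis, iron and histone lists did. Histones also passed with quantile normalization, and glycolysis by ranks, with each of the 3 scalings and without heat shock replicate 1. Of 25 genes of the unfolded protein response INO1, for inositol synthesis, was higher by 2.69 ± 0.24 (SE, n = 2 per treatment) and 0 were lower (2 and 0 adjusted over the list alone; limma camera adjusted p = 0.839). No member was called in 5 lists, and the limma camera adjusted p was 0.0615 for 18 glycolysis genes, 0.153 for 25 iron genes, 0.153 for 48 citric acid cycle genes, 0.25 for 9 histone genes and 0.684 for 25 ergosterol genes. Adjusted over the list alone, 1 glycolysis gene was lower, 3 citric acid cycle genes were higher and 4 lower, and 0 were called in the iron, histone and ergosterol lists. Of 12 reference genes 0 were called, 0 also adjusted over the list alone (limma camera adjusted p = 0.947), with a median of 0.06 and a mean of −0.13. The citric acid cycle list had a median of 0.11 and a mean of −0.00.

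**Figure D2:**
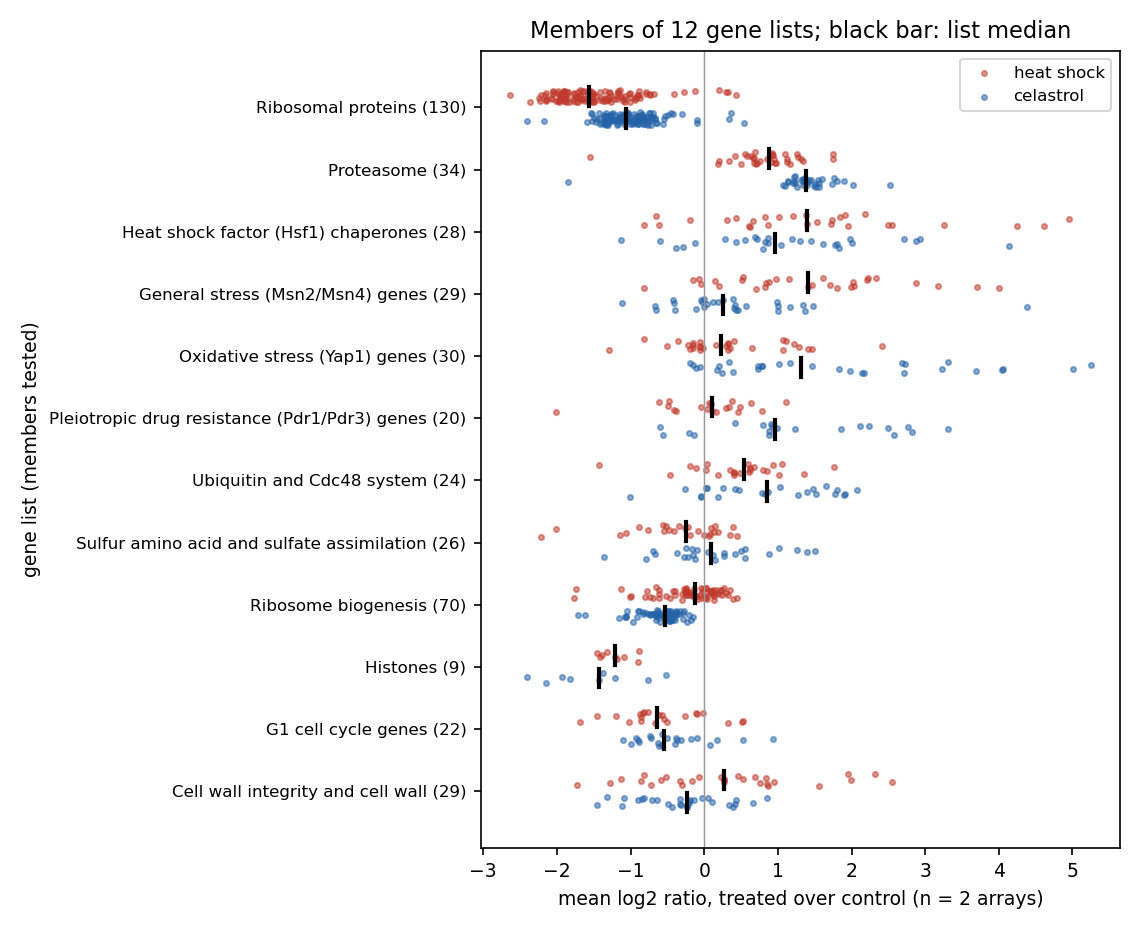
Mean log2 ratio of treated over control over 2 arrays (x axis) for each gene of 12 lists (y axis), heat shock in red and celastrol in blue, with a black bar at each list's median. Medians for Yap1 genes are 0.23 after heat shock (0.0517 without replicate 2) and 1.32 after celastrol, for general stress genes 1.40 and 0.25, for proteasome genes 0.88 and 1.38, and for ribosomal protein genes −1.57 and −1.06.

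In all, limma called 60 of 5403 genes for the difference, 29 higher and 31 lower after celastrol, and 741 had an unadjusted p under 0.05. The smallest difference that was called was 1.65 log2 units, and the treatments also differed in length, at 30 min against 1 h. Without either celastrol array the count was 0 by limma, with 378 and 343 genes at an unadjusted p under 0.05 without replicates 1 and 2, and it was 175 and 575 without heat shock replicates 1 and 2. Of the 30 calls of named genes, all were lost without either celastrol array and 10 in a test against a 1.5-fold change. GRE2, HSP12, PDR5, CWP1 and CPA1 lost theirs with exact zeros kept as values, GRE2, SSA3 and PST1 with equal spread of the arrays, and PDR5 with genes measured on at least 1 array per treatment.

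The responses were also set side by side over all genes. Mean ratios after heat shock and celastrol correlated across 5403 genes with r = 0.57 (Spearman's rho = 0.59), and those of the 711 probes without a gene with r = 0.65 (rho = 0.70). Without a dye swap, a bias shared by all arrays would raise these values. Single arrays of different treatments correlated with r = 0.45 to 0.57. The highest was heat shock replicate 1 with celastrol replicate 2. In probes without a gene this pair had r = 0.67, against 0.65 for the heat shock replicates. The mean ratios of genes had r = 0.51 without heat shock replicate 1 and 0.50 without celastrol replicate 2. Without heat shock replicate 2 or celastrol replicate 1, r was 0.54 and 0.60. A deviation shared by only some arrays was not tested. Called genes that rose in both treatments numbered 49, where independent lists would share 8.89 (odds ratio 8.48, Fisher's exact test p = 2.43e-24). Those that fell in both numbered 59, against 6.95 (odds ratio 17.3, Fisher's exact test p = 1.42e-41). Both lists of calls use the same spread per gene, so they are not independent by design. The chaperone genes SSA4, HSP26, HSP104, HSP82, HSP42 and SSA3, the proteasome gene ECM29, the pump gene PDR5 and ECM4 were among those that rose in both. HTA2, HTB2, HHF1, RPP2B, RPS22A, MET17 and DBP2 were among those that fell in both. All of these belong to the set of 357 genes low on all arrays, described above. SAM3 also fell in both and lies outside that set.

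Genes called in opposite directions were few and were named after their values were seen. CHA1 (2.15 after heat shock, −2.54 after celastrol), ARO9 (1.9995, −0.84), RGS2 (1.35, −0.93) and TDA6 (1.32, −1.48) rose after heat shock and fell after celastrol, 4 against 6.2 for independent lists (Fisher's exact test p = 0.529). MET28 (−0.88, 1.40), HXT6 (−0.99, 1.30) and YLR460C (−1.13, 1.82) fell after heat shock and rose after celastrol, 3 against 9.97 (Fisher's exact test p = 0.0187). Of the 231 genes that rose after heat shock, 176 were above 0 after celastrol, and by the test of the difference itself 28 were lower and 3 higher after celastrol. Of the 208 genes that rose after celastrol, 166 were above 0 after heat shock, and 28 were higher and 1 lower after celastrol by that test.

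**Figure D3:**
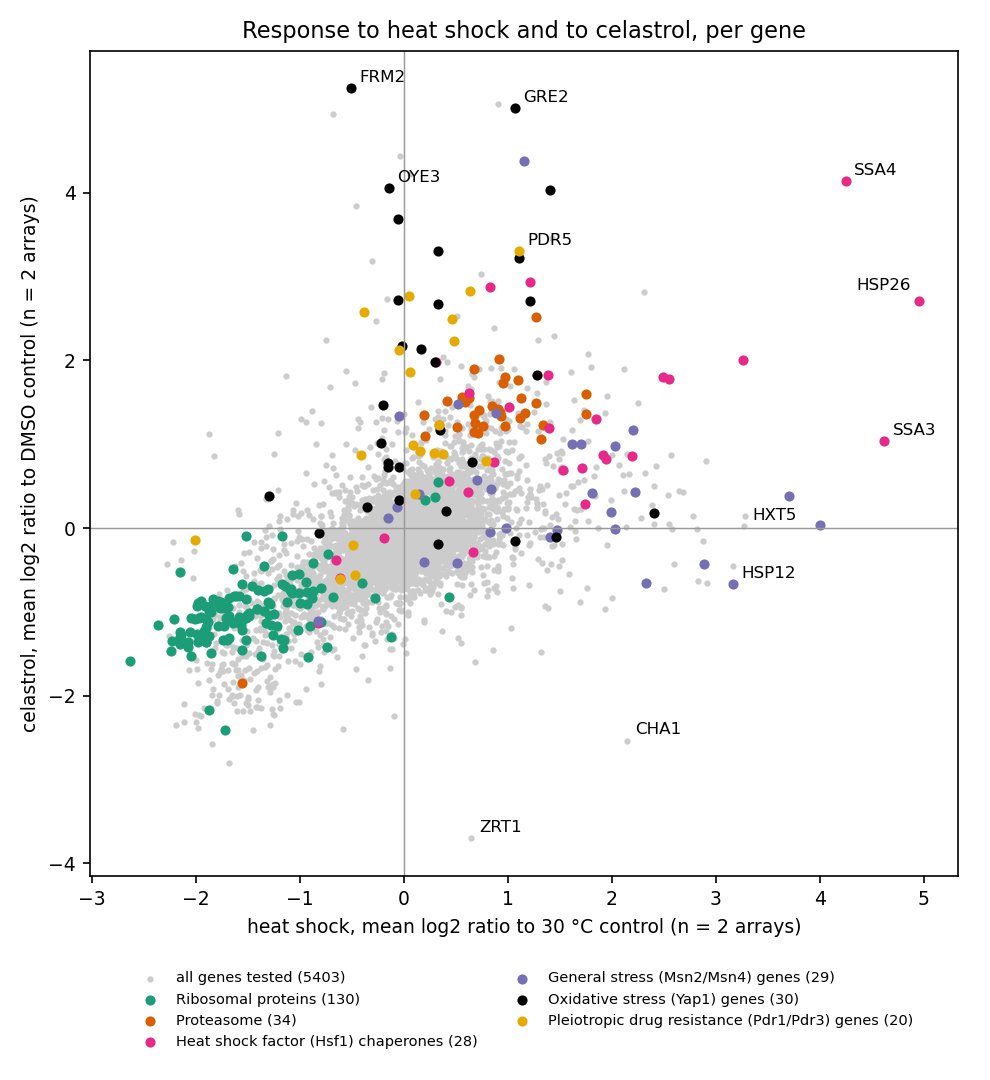
Mean log2 ratio after heat shock (x axis) against that after celastrol (y axis) for 5403 genes, each a point over 2 arrays per treatment, with 6 gene lists in colour. SSA4 stands high on both axes at 4.25 and 4.14, FRM2 only on the celastrol axis at −0.51 and 5.25, HSP12 only on the heat shock axis at 3.17 and −0.67, and ZRT1 lowest after celastrol at −3.70.

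The overlap depended on single arrays and on the genes low throughout. It was 0 in both directions without either celastrol array, by the loss of all limma calls, and without heat shock replicates 1 and 2 it was 92 and 207 higher and 144 and 515 lower. Leaving out the 357 genes low on all 4 arrays, which by construction removes genes that fell in both, gave 79 higher and 22 lower and r = 0.42. With a 2-fold change in both arrays of each treatment in place of the adjusted p, 28 genes were higher and 40 lower in both.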

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

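The probes without a gene in the annotation were looked at after the gene results were seen, and the tests of probe order, of faint spots and of the quartile of the difference were chosen after the result was seen, the others before.

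Probes that have no gene in the annotation were fitted with all other probes but enter no gene result. Of the 711 such probes measured on all arrays, limma called 50 after heat shock (10 higher and 40 lower), 53 after celastrol (10 higher and 43 lower) and 2 for the difference, both higher after celastrol. The highest, probe 15320, had a log2 ratio of 5.46 ± 0.97 after celastrol (SD, n = 2, limma adjusted p = 0.00431) and 0.71 after heat shock. A sequence for this probe would tell which transcript it measures.

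A set of probes lay below 0 on all 4 arrays in both treatments, and 99 of its 357 genes encode ribosomal proteins. Faint spots stay open. Probes with a faint spot on heat shock replicate 1 were higher than other probes with a recovered intensity on the other 3 arrays, by 0.0364 (interval 0.00198 to 0.0699). The recovered intensity covers only the control channel of that array and 51.6% of its values. A bright spot can also reduce to a small whole number, so this comparison cannot decide it. Position in the print or in oligo plates could add to the low set and also stays open. Mean ratios of probes 12 places apart in the probe order correlated with r = 0.0510, above the largest of 1000 random orders at 0.0365. Those 11 and 13 places apart gave 0.0470 and 0.0501. If the set were transcripts that fell in both treatments, genes silent in growing cells might be rare in it, and 3.57% of 56 meiosis genes (2 genes) belonged to it against 6.64% of all other genes, 4.91% of these without ribosomal protein genes and 13.8% of probes without a gene, with an exact interval of 0.436 to 12.3% that leaves this open. A dye swap would test whether the low ratios follow the treatment or the dye, but would not tell faint spots from position.

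General stress genes under Msn2 and Msn4 were higher after heat shock and mostly not called after celastrol, with 22 of 29 below 0 in the difference. A dye or probe bias of equal size on all arrays would cancel in the difference. Such a bias cannot give the median difference of −0.925, with an upper quartile of −0.129 (−0.018 on median-centred arrays). The pattern is itself a difference between treatments, so this follows from it and is not a separate test. A bias that differed between arrays was not tested. The different length of treatment could explain the pattern. Of the celastrol arrays, 0 were taken at the time of the heat shock arrays, so this cannot be tested here. Celastrol samples taken at 30 min would decide it.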

How the results depend on the processing

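Counts by limma depended on the scale of the arrays and on single arrays. With a celastrol array left out, the spread came from the heat shock arrays alone. With a heat shock array left out, it came from the celastrol arrays alone. Heat shock calls in the full fit thus rest in part on the spread of the celastrol arrays, which correlated with r = 0.85 against 0.66. The cause of the dependence on scale was not tested. Quantile normalization gave 989 genes for heat shock, 1135 for celastrol and 164 for the difference, equal spread 881, 1093 and 117, and omission of genes with replicates over 1 log2 apart, which lowers the spread by construction, 1188, 1226 and 358. A block for the replicate number gave 30, 65 and 0 (1293, 1281 and 524 with an unadjusted p under 0.05) and kept 48 of the 153 calls of named genes, losing 42, 33 and 30, and the deviations of same-numbered arrays correlated with −0.31. The crossed block gave 849, 798 and 50 and lost 0, 0 and 3 calls of named genes. Array weights gave 216 for heat shock and 1243 for celastrol, and a test against a 1.5-fold change 69, 60 and 31. Fitted alone, heat shock had 0 calls (1154 with an unadjusted p under 0.05) and celastrol 1522. With an array left out, counts ran from 0 to 1582 for heat shock, 0 to 1522 for celastrol and 0 to 575 for the difference, and the 0 counts left 1154, 411 to 926 and 343 to 378 genes with an unadjusted p under 0.05. Without the 357 genes low on all arrays the difference had 132 genes, the correlation of responses was 0.42, and overlaps were 79 higher and 22 lower. With an array left out the correlation ran from 0.50 to 0.60 and overlaps from 0 to 207 higher and 0 to 515 lower; by 2-fold changes 28 were higher. Camera called 0, 0 and 0 lists with an estimated correlation, and with an array left out 6 to 13, 12 to 13 and 9 to 14. The setting with an estimated correlation tests on only 2 residual degrees of freedom. The ubiquitin list lost its call after heat shock there, although its estimated correlation of −0.0163 lay under the preset 0.01. Results that turned direction were never called. List medians, where camera's direction turned, follow, with ranges over left-out arrays. After heat shock the unfolded protein response had 0.0624 without low genes, ergosterol 0.17 without heat shock replicate 2, glycolysis −0.0355 by quantiles, 0.00936 with equal spread and −0.363 to 0.20, and reference genes −0.120 to 0.0377. After celastrol iron had −0.0742 without replicate 1, where camera turned, and 0.108 without replicate 2, mating −0.26 to 0.0428, copper and zinc −0.186 to −0.0292, and reference genes −0.23 by ranks and up to −0.0115. In the difference the unfolded protein response had −0.10 to −0.0865, ergosterol −0.294 to 0.10, histones 0.25 without low genes, and reference genes −0.17 to 0.0927. Genes after heat shock had −0.23 to 0.87 (TRX2), −0.19 to 0.0859 (TRR1), −0.45 to 0.0559 (GSH1), −0.47 to 0.17 (OYE3) and −0.12 to 0.00383 (FLR1). CTT1 after celastrol had 0.11 median-centred, 0.0759 by quantiles, 0.0188 with equal spread and −0.13 to 0.13, and CUP1-1 0.0352 median-centred. In the difference SSA4 had 6.94e-05 median-centred, 0.0288 with equal spread and −0.63 to 0.41, HSP42 −0.58 to 0.18, and MET17 −0.60 to 0.17. The alternative for linear ratios was not run, because the values go below 0 and were taken as log2.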

Other observations

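The gene lists of this section were written after values of some members had been seen, so their tests run on the members not seen before; for the other members counts and values alone are given, and these tests were chosen after the result was seen, except those of the purine pattern.

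Purine and one-carbon genes under Bas1 rose after heat shock in 8 of 18 cases and fell in 0. ADE17, for the last steps of purine synthesis, rose by 2.92 ± 0.45, the folate enzyme gene MTD1 by 2.88 ± 0.39, GCV1, for the glycine cleavage system, by 2.82 ± 0.59 and ADE2 by 2.39 ± 0.62 (all SD, n = 2). In celastrol minus heat shock 4 of the 18 were lower, with MTD1 at −3.04 and GCV1 at −2.84, and after celastrol 1 rose and 1 fell. Among the 13 members not seen before, the limma camera adjusted p over 6 lists was 0.248 after heat shock, 0.952 after celastrol and 0.043 for the difference (adjusted p = 0.44 with an estimated correlation). Aminoacyl-tRNA synthetase genes, whose enzymes charge tRNAs with amino acids, fell after heat shock in 8 of 18 cases, SES1, for seryl-tRNA synthetase, by 1.53 ± 0.13 and THS1, for threonyl-tRNA synthetase, by 1.52 ± 0.06 (both SD, n = 2). Of the 12 not seen before 2 fell, with a median of −0.47 (limma camera adjusted p = 0.00153, adjusted p = 0.522 with an estimated correlation). None of the 18 was called after celastrol or for the difference, and for the 12 the limma camera adjusted p was 0.176 and 0.0256 (adjusted p = 0.447 with an estimated correlation for the difference).

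Of 17 hexose transporter genes 5 rose and 1 fell after celastrol. HXT3, for a low-affinity glucose transporter, rose by 2.24 ± 0.21 (SD, n = 2) and differed from heat shock by 2.99 (limma adjusted p = 0.023), and HXT4 rose by 1.31 ± 0.17 (SD, n = 2). HXT6 (1.30 ± 0.07) and HXT7 (1.20 ± 0.10; both SD, n = 2) rose too, but are near-identical. After heat shock 1 rose and 2 fell, HXT2 to −2.03 ± 0.26 (SD, n = 2), and for the difference 4 were higher and 1 lower. The 10 not seen before had a limma camera adjusted p of 0.487 after heat shock, 0.73 after celastrol and 0.601 for the difference. In the list written for Pho4, 6 of 18 phosphate genes fell after celastrol. Among them were the acid phosphatase genes PHO3 (−2.40 ± 0.28) and PHO5 (−2.07 ± 0.48) and the phosphate transporter gene PHO84 (−1.035 ± 0.12; all SD, n = 2). Control of each member by Pho4 was not tested. After heat shock 3 of the 18 rose, including PHM8 at 2.13 ± 0.44 (SD, n = 2). Of the 11 not seen before 1 fell after celastrol (limma camera adjusted p = 0.124) and 1 rose after heat shock (adjusted p = 0.278), and in the difference their median was −0.64 with 0 called (adjusted p = 0.0051, adjusted p = 0.437 with an estimated correlation). The fatty acid synthase genes FAS1 and FAS2 fell after heat shock (−1.73 ± 0.21 and −1.68 ± 0.20) and after celastrol (−1.02 ± 0.22 and −1.38 ± 0.51), and the acetyl-CoA carboxylase gene ACC1 fell after heat shock (−1.496 ± 0.07; all SD, n = 2). None of the 9 other fatty acid genes was called, and their limma camera adjusted p was 0.664, 0.124 and 0.294 for heat shock, celastrol and the difference. Of 56 meiosis genes, none seen before, 2 fell after heat shock, 1 rose and 2 fell after celastrol, and 0 were called for the difference (limma camera adjusted p = 0.664, 0.0108 and 0.0151, adjusted p = 0.886, 0.581 and 0.485 with an estimated correlation). Among the genes named here for a fall, SES1, THS1, HXT2, PHO3, PHO5, FAS1 and FAS2 belong to the set of 357 genes low on all arrays.

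The purine pattern could come from the choice of a list after seeing its highest members. Among the 13 members not seen before, 3 rose after heat shock and 9 lay above 0 (limma camera p = 0.0828, p = 0.208 with an estimated correlation), so chance choice is not excluded. A dye or probe bias of equal size on all arrays would cancel in celastrol minus heat shock. There these 13 had a median of −0.425. Their upper quartile of −0.005 rose to 0.107 on median-centred arrays, which leaves such a bias open. A further heat shock series with dyes swapped would test it.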
